A study of Homo sapiens with 6 samples.

How the data were processed

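Transcript levels were measured on 6 one-colour oligonucleotide arrays. Per the labels, 3 arrays carried RNA of undifferentiated H9 cells and 3 carried RNA of mesodermal progenitors, which had been made from H9 cells and sorted by flow cytometry on day 3.5. The labels' protocols name a silica-column micro kit for RNA and a kit that makes biotinylated cRNA in an amplification step. Each deposited value is an intensity on a linear scale, as the values themselves show. The method that summarised the probes of a probe set, the background correction and any scaling between arrays are not given in the sources used here. Of the deposited values, 2.15% equalled 1, the lowest value in the table, so that low levels were cut off at that floor.

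The table held 54675 probe sets. Of these, 41097 were annotated to 1 gene symbol, 1801 to several and 11777 were not listed with a gene in the annotation table. The 62 array controls among all probe sets were left out of the gene tests. Symbols of 41043 of the 1-gene probe sets were updated through their gene identifier, and the other 54 kept the annotated symbol. No gene was named from a probe set annotated to several genes. Each gene was represented by the probe set with the highest mean over the 6 arrays among those annotated to it alone, which gave 19775 genes. Some members of the gene lists, among them POU5F1 and most HOXA genes, are not analysed here.

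The authors' deposited intensities were converted to log2(intensity + 16). The medians of the 6 arrays spanned 0.1495 on this scale, above the limit of 0.1 that had been set, and the arrays were therefore quantile-normalized. A log2 change is the mean of the progenitor arrays minus the mean of the hESC arrays on this scale, and it understates the change of genes with a low level. The number of arrays, 3 per group, limits the precision. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

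Genes were tested with lmFit and eBayes of limma (version 3.58.1, R 4.3.3), two-sided, with the Benjamini-Hochberg adjustment over all genes tested and a call at an adjusted p under 0.05. The fit held the 6 arrays in 2 groups and no covariate. For 22 gene lists the members past the threshold were counted over all genes tested and, separately, with the adjustment made over the list alone. Each list was also tested as a set with camera of limma, at a preset correlation between genes of 0.01, with adjustment over the 22 lists, and again with a correlation estimated from the data. Values of array controls were compared with an exact permutation test, two-sided, for which 0.1 is the smallest p that 3 arrays against 3 allow. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

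The groups, the tests, the gene lists and all alternatives except those named below were chosen before the data were examined. So was the rule for the genes named in the text. It took the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold whose groups did not overlap, a fixed set of lineage genes, and for each list the 4 members with the largest change past the threshold, the largest one in the opposite direction and the 2 brightest members that did not pass. Genes beyond this rule are said to have been chosen after their values were seen. For 7 of the 145 named genes another probe set of the same gene passed the threshold in the opposite direction.

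The alternatives covered 2 filters that left out the dimmest 30% or 50% of genes, no normalization between arrays, and pseudocounts of 1 and 64. In another, called median centring, each array was centred on the median of its gene values, not of all its probe sets. The rest were other ways to choose a gene's probe sets, 2 other variance models, the replicate number as a block, and leaving out each array. Lists were also tested with ranks. Probe sets were also tested singly, and genes were also called at an adjusted p under 0.01. Alternatives chosen after seeing the data were the average of progenitor arrays 2 and 3 used as 1 array, and a scaling of each array on its biotin hybridization controls, those named bioB, bioC and bioD, without the cre controls.

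The gene test was tested on simulated data for this comparison, with 19775 genes of which 50 each had a known change. It recovered 22% of the genes at a log2 change of 0.5, 84% at 1, 98% at 2 and 100% at 4, and it called 11 of 19555 unchanged genes. In the same simulation the list test called the 1 list that had been shifted and 1 of 21 lists that had not. The simulation left 19555 of 19775 genes unchanged, whereas 47.9% of genes were called in the data, and the adjustment depends on that share. It also drew the noise of each gene independently. The recovery shares therefore need not hold for the data, and the list result does not cover genes that vary together.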

Results

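Gene expression was compared between undifferentiated H9 cells, an established line of human embryonic stem cells (hESC), and mesodermal progenitors made from them in medium with activin A, BMP4, FGF2 and VEGF. The progenitors had been sorted on day 3.5 for lacking CD326, the epithelial cell adhesion molecule EPCAM, and for carrying CD56, the neural cell adhesion molecule NCAM1. Each group had 3 arrays, with median deposited intensities of 31.0 to 31.2 in the progenitors and 33.1 to 36.1 in hESC. After normalization the first principal component held 90.2% of the variance and separated the groups. Across genes, which are not independent replicates, arrays of a group correlated at r = 0.991 to 0.997 and arrays of different groups at r = 0.904 to 0.920. Progenitor arrays 2 and 3 were the closest pair, with 7 genes more than 2-fold apart, against 208 genes between progenitor arrays 1 and 2 and 180 between 1 and 3.

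The antigens used for the sort check the labels and are no finding. NCAM1 was at 10.28 ± 0.21 (log2 level, SD, n = 3) in the progenitors and 6.82 ± 0.13 in hESC, an increase of 3.46. EPCAM was at 9.35 ± 0.19 in the progenitors and 11.69 ± 0.05 in hESC, and its log2 change was -2.33. Progenitor array 1 had the highest NCAM1, at 10.53 against 10.15 and 10.17, and the lowest EPCAM, at 9.14 against 9.47 and 9.45.

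The comparison asked how the transcriptome of the sorted progenitors differed from that of the stem cells they came from. The genes with the largest increases included the receptor APLNR, transcription factors such as HAND1, and the matrix genes HAPLN1 and LUM. Those with the largest decreases included the pluripotency factor PRDM14 and the nodal inhibitor LEFTY1. On the log2(intensity + 16) scale, APLNR, the apelin receptor, rose by 7.61 (SE 0.11, n = 3 per group) and HAND1, a transcription factor of lateral and cardiac mesoderm, by 7.54 (SE 0.13). The hyaluronan link protein HAPLN1 rose by 7.12, the matrix proteoglycan lumican (LUM) by 7.06 and the BMP-binding protein BMPER by 7.05. The transcription factors MSX1, HOXB2, GATA6, GATA2, LEF1, ISL1 and SNAI2 completed the 12 largest increases on this scale, with log2 changes from 6.99 for MSX1 to 6.21 for SNAI2. The sizes and the order of these increases depended on the pseudocount, since several genes were near the floor in hESC, such as LUM at a mean intensity of 1.58 and HOXB2 at 3.20. LUM, the 4th largest increase at a pseudocount of 16, rose by 9.86 at a pseudocount of 1, the largest there, and by 5.19 at 64, the 9th. Among the decreases, the neuronal kinesin KIF1A led with -5.82, followed by the nodal inhibitor LEFTY1 at -5.33 and the antisense RNA JAKMIP2-AS1 at -5.30. The order of the decreases depended on the pseudocount too. JAKMIP2-AS1 was the largest decrease at a pseudocount of 1 (-7.22) and the 9th at 64 (-3.65). PRDM14, a repressor that maintains human pluripotency, changed by -4.85, the tryptophan-degrading enzyme IDO1 by -4.48 and skeletal muscle actin (ACTA1) by -5.27. The long noncoding RNAs MIAT and FOXD3-AS1 changed by -4.85 and -4.79.

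**Figure D1:**
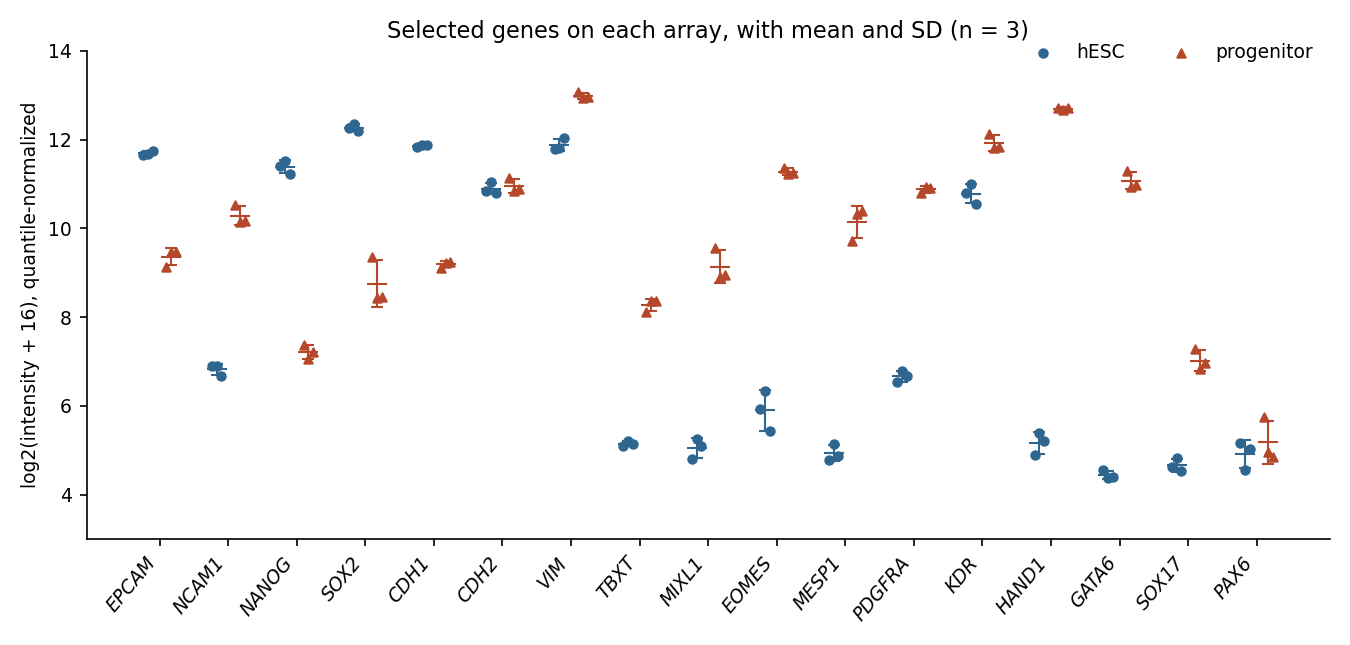
Log2(intensity + 16) of 17 named genes on each array after normalization, with circles for hESC arrays, triangles for progenitor arrays and bars for the mean and SD of 3 arrays. HAND1 stood at 12.70 in the progenitors and 5.16 in hESC, while CDH2 overlapped between the groups.

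Of 19775 genes, 9463 (47.9%) differed between the groups at an adjusted p under 0.05 with limma, 5278 higher and 4185 lower in the progenitors. At least 2-fold changes were found for 1857 higher and 1427 lower genes. Larger changes were more often increases on this scale, with 269 genes higher and 110 lower at 8-fold or more, and 52 higher and 4 lower at 32-fold or more. In 11339 genes the 3 arrays of one group lay all above those of the other, where chance gives 10% of genes. The share of higher genes among those called, 55.8%, moved with the scaling of the arrays. It was 37.2% when each array was centred on the median of its gene values. It was 82.0% when arrays were scaled on their hybridization controls, an alternative chosen after seeing the data. These scalings put the median change of all genes at -0.15 and 0.32, against 0.04 on the quantile-normalized scale, on which all changes are given.

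Pluripotency genes fell as a group. Of 28 measured members of the list, 26 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone, and the median change was -1.78 (camera adjusted p = 2.39e-14). NANOG, a core factor of the pluripotency network, fell by 4.17 (SE 0.12), and SOX2, another core factor, fell by 3.52 (SE 0.24). POU5F1 (OCT4), also on the list, was not among the measured members and is not analysed here. The deubiquitinase USP44 fell by 4.17. LIN28B, an RNA-binding protein that blocks let-7 maturation, was the member that rose, by 0.49, and the zinc finger factor SALL4 differed by -0.29 without passing the test, which it passed without progenitor array 1 (-0.50, adjusted p = 0.0473). SOX2 was higher on progenitor array 1, at 9.36, than on arrays 2 and 3, at 8.42 and 8.46, and hESC arrays lay between 12.19 and 12.35. The list as a whole was higher on that progenitor array by a median of 0.14, and hESC arrays 2 and 3 differed from the other hESC arrays by 0.057 and -0.064.

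Genes of the primitive streak and nascent mesoderm rose. Of 23 measured, 17 rose, 2 fell and 4 did not pass, also adjusted over the list alone, with a median change of 3.13 (camera adjusted p = 2.27e-07). TBXT (brachyury), MIXL1, EOMES and MESP1, transcription factors that mark cells entering the mesoderm, rose by 3.13, 4.09, 5.38 and 5.22. The LIM homeodomain factor LHX1 and the WNT-responsive factor SP5 rose by 5.74 and 5.53, whereas the posterior streak factor EVX1 fell by 1.96. The other member that fell, chosen after its value was seen, was GDF3 (-1.17), a ligand of the nodal pathway.

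Lateral plate and cardiac mesoderm genes rose too, 20 of 25, with 1 lower and 4 not past the test, and with 21 higher and 1 lower adjusted over the list alone (median 4.21, camera adjusted p = 1.43e-11). Besides HAND1, GATA6 and ISL1, the T-box factor TBX3 rose by 6.13 and PDGFRA, a growth factor receptor of mesenchymal cells, by 4.21 (SE 0.10). TBX5, a T-box factor of the heart and forelimb, was the member that fell, by 0.43, and its direction turned when probe sets that can match several transcripts were left out (0.053, adjusted p = 0.816). It did not pass without hESC array 1 (-0.37, adjusted p = 0.0673), on the mean of its probe sets (-0.058) or with scaling on hybridization controls (-0.19) either. TBX2 and MEF2C did not pass, at 0.52 and 1.33. TBX2 passed without hESC array 2 (0.74) or 3 (0.55), where another of its probe sets was the brightest, so that these calls do not come from the left-out array alone. It also passed on the mean of its probe sets (0.60) and without probe sets that can match several transcripts (0.66). Array weights (1.06) and scaling on hybridization controls (0.88) gave a call for TBX2 too. MEF2C, at 7.26 on progenitor array 1 and at 4.99 and 5.28 on the others, passed without progenitor array 1 (0.63) or 2 (1.76). Of 17 paraxial and somitic genes 5 rose, 2 fell and 10 did not pass, also adjusted over the list alone, and the list was not called (median 0.20, camera adjusted p = 0.227). The NOTCH ligand DLL3 and the forkhead factor FOXC2 rose by 3.93 and 2.38, TBX6 rose by 1.36, and LFNG, a glycosyltransferase that modifies NOTCH, fell by 2.17. Chosen after their values were seen, DLL1 (1.31) and PAX7 (1.16) completed the paraxial genes that rose, and TCF15 (-0.59) those that fell. TCF15 did not pass without progenitor array 2 (-0.55, adjusted p = 0.0502) or with scaling on hybridization controls (-0.38). PAX1, a sclerotome factor, and the somite boundary gene RIPPLY1 did not pass, at -0.30 and 0.01.

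**Figure D2:**
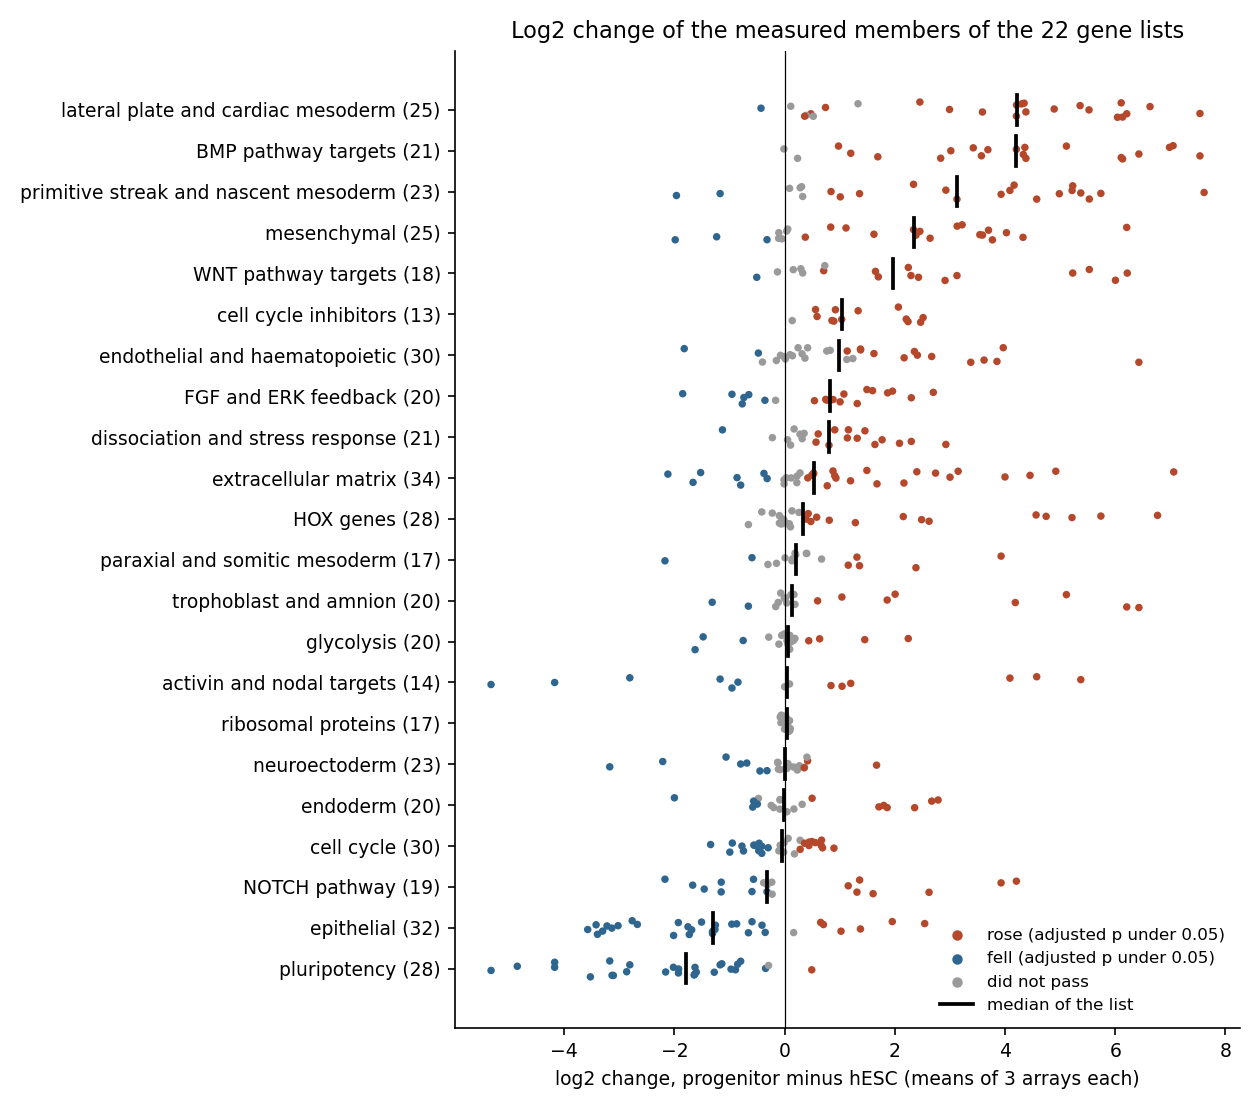
Log2 change of each measured member of the 22 gene lists, progenitor minus hESC, as points coloured by whether the gene rose, fell or did not pass, with the number measured in brackets and a bar at each list's median. Medians ran from -1.78 for pluripotency genes to 4.21 for lateral plate genes and BMP targets.

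Targets of BMP and WNT signalling were higher in the progenitors. Of 21 BMP targets 19 rose, none fell and 2 did not pass, also adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 in limma (median 4.21, camera adjusted p = 3.66e-13). MSX1, BMPER, HAND1 and GATA2 led this list, and GREM1, a BMP antagonist, and DLX3 did not pass, at 0.24 and -0.01. GREM1 was at 7.60 on progenitor array 1 and at 6.13 and 6.16 on the other progenitor arrays, and its difference turned to -0.25 without array 1. Of 18 WNT targets 12 rose, 1 fell and 5 did not pass, also adjusted over the list alone (median 1.97, camera adjusted p = 4.02e-06). LEF1, a nuclear partner of beta-catenin, and the WNT antagonist DKK1 rose by 6.22 and 5.23, and the R-spondin receptor LGR5 rose from a mean intensity of 4.74 in hESC to 1276 in the progenitors. ZNRF3, a ligase that removes WNT receptors, fell by 0.50, and its sign turned when arrays were scaled on hybridization controls (0.011). AXIN2, a feedback inhibitor of WNT signalling, differed by 0.30 without passing, and by 0.15 without progenitor array 1. It passed, at 0.84, with scaling on hybridization controls, while another of its probe sets fell by 0.38.

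Activin and nodal targets moved both ways. Of 14 measured, 6 rose, 6 fell and 2 did not pass, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.642), with a median of 0.05, a mean of 0.14 and a test pointing down. CER1, a secreted inhibitor of nodal, BMP and WNT, rose by 4.58 with EOMES and MIXL1, while LEFTY1 and NANOG fell. Of the 18 listed members 13 were also on other lists, so most of these changes are counted there too. CER1, EOMES and MIXL1 were also on the streak list, and LEFTY1 and NANOG on that of pluripotency. The activin and nodal list was higher on progenitor array 1 than on the other progenitor arrays by a median of 0.20. On hESC arrays 2 and 3 it differed from the other hESC arrays by 0.19 and -0.23. Of 20 FGF and ERK feedback genes 13 rose, 6 fell and 1 did not pass, also adjusted over the list alone, with a median of 0.82 and no call (camera adjusted p = 0.0726). The list was called when each array was centred on the median of its gene values (adjusted p = 0.00807) and without normalization between arrays (0.0477). SPRED2 and SPRY2, inhibitors of RAS and ERK signalling, rose by 2.70 and 1.87, and the immediate-early factor EGR1 and the ERK phosphatase DUSP5 by 2.30 and 1.96, whereas the receptor FGFR4 fell by 1.85. Of 19 NOTCH pathway genes 7 rose, 8 fell and 4 did not pass, with 7 higher and 10 lower adjusted over the list alone. The NOTCH list was not called (camera adjusted p = 0.507), with a median of -0.32, a mean of 0.31 and a test pointing down. HEY1 and HEY2, transcriptional repressors downstream of NOTCH, rose by 4.21 and 2.62.

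Epithelial genes fell and mesenchymal genes rose. The progenitors had been sorted for lacking EPCAM, itself an epithelial gene, and no unsorted cells of day 3.5 were measured. The comparison therefore cannot separate the sort from the differentiation. Of 32 epithelial genes 25 fell, 6 rose and 1 did not pass, also adjusted over the list alone (median -1.31, camera adjusted p = 1.01e-07, and adjusted p = 0.0841 with an estimated correlation). E-cadherin (CDH1) fell by 2.67 (SE 0.08), and the splicing regulator ESRP1 and the tight junction genes MARVELD3 and CLDN7 fell, with changes of -3.42, -3.57 and -3.30. Keratin KRT19 rose by 2.54, and so did the simple keratins KRT8, by 1.95, and KRT18, by 1.38, chosen after their values were seen. Of 25 mesenchymal genes 17 rose, 3 fell and 5 did not pass, also adjusted over the list alone (median 2.34, camera adjusted p = 7.86e-05). SNAI2, ZEB2 and TWIST1, transcription factors that repress epithelial genes or drive the mesenchymal state, rose by 6.21, 4.03 and 3.77, and cadherin CDH11 by 4.33. Vimentin (VIM) rose by 1.11 (SE 0.10), THY1 fell by 1.98, as did TAGLN (-1.23) and TPM1 (-0.32), chosen after their values were seen, and N-cadherin (CDH2) differed by 0.06 (SE 0.12) without passing. TAGLN did not pass when probe sets that can match several transcripts were left out (-0.17), and TPM1 turned, to 0.16, without passing, when arrays were scaled on hybridization controls. CDH2 passed, at 0.51, when arrays were scaled on hybridization controls.

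Of 34 extracellular matrix genes 20 rose, 7 fell and 7 did not pass, with 22 higher and 7 lower adjusted over the list alone (median 0.53, camera adjusted p = 0.00441). The call was lost at an adjusted p = 0.375 with an estimated correlation. Besides LUM, the collagens COL3A1 and COL5A1 and the basement membrane protein NID2 rose by 4.92, 4.00 and 4.45, and thrombospondin THBS1 fell by 2.12. The matrix list was higher on hESC array 2 than on the other hESC arrays by a median of 0.15, with -0.14 on hESC array 3, and COL3A1 stood there at 7.63, against 6.14 and 5.34, so that its increase was 5.56 without that array.

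Endothelial and haematopoietic genes were higher in part. Of 30 measured, 13 rose, 2 fell and 15 did not pass, with 14 higher and 3 lower adjusted over the list alone (median 0.98, camera adjusted p = 0.00503). The list was no longer called, at an adjusted p = 0.465 with an estimated correlation, nor when the dimmer 50% of genes were left out (adjusted p = 0.0825). GATA2, LMO2, CDH5 (VE-cadherin) and SOX7, genes of early blood and vessel cells, had the largest increases, with 3.97 (SE 0.37) for LMO2, 3.85 (SE 0.75) for CDH5 and 3.62 (SE 0.52) for SOX7. KDR, the VEGF receptor of vascular progenitors, was high in both groups, at 11.92 in the progenitors and 10.78 in hESC, and rose by 1.14 (SE 0.14). SPN, a leukocyte sialoprotein, fell by 1.82 on its brightest probe set and did not pass on the mean of its probe sets (-0.29). The other member that fell was ITGA2B (-0.48), a platelet integrin, chosen after its value was seen, which did not pass with scaling on hybridization controls (-0.12), on the mean of its probe sets (-0.20) or without hESC array 1 (-0.41). When probe sets that can match several transcripts were left out, LMO2 did not pass (0.13, adjusted p = 0.581). EGFL7 and the VEGF receptor FLT1 did not pass, at 1.13 and 0.42, nor without progenitor array 1, at 0.41 and 0.22. Both passed with scaling on hybridization controls (1.63 and 0.87), and FLT1 also with another variance model in limma (adjusted p = 0.0324). Another probe set of FLT1 fell by 2.38.

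These genes stood apart on progenitor array 1. CDH5 was at 10.01 there and at 6.90 and 7.12 on arrays 2 and 3, and SOX7 was at 10.07 against 7.96 and 8.08. Of the 30 genes 26 were higher on array 1 than on the mean of the other two, by a median of 0.54. Without array 1, 13 members were higher and 3 lower, and the list remained called (adjusted p = 0.00192), but its median was 0.41 in place of 0.98. The increase of CDH5 was then 2.85, that of SOX7 2.92 and that of LMO2 3.49.

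**Figure D3:**
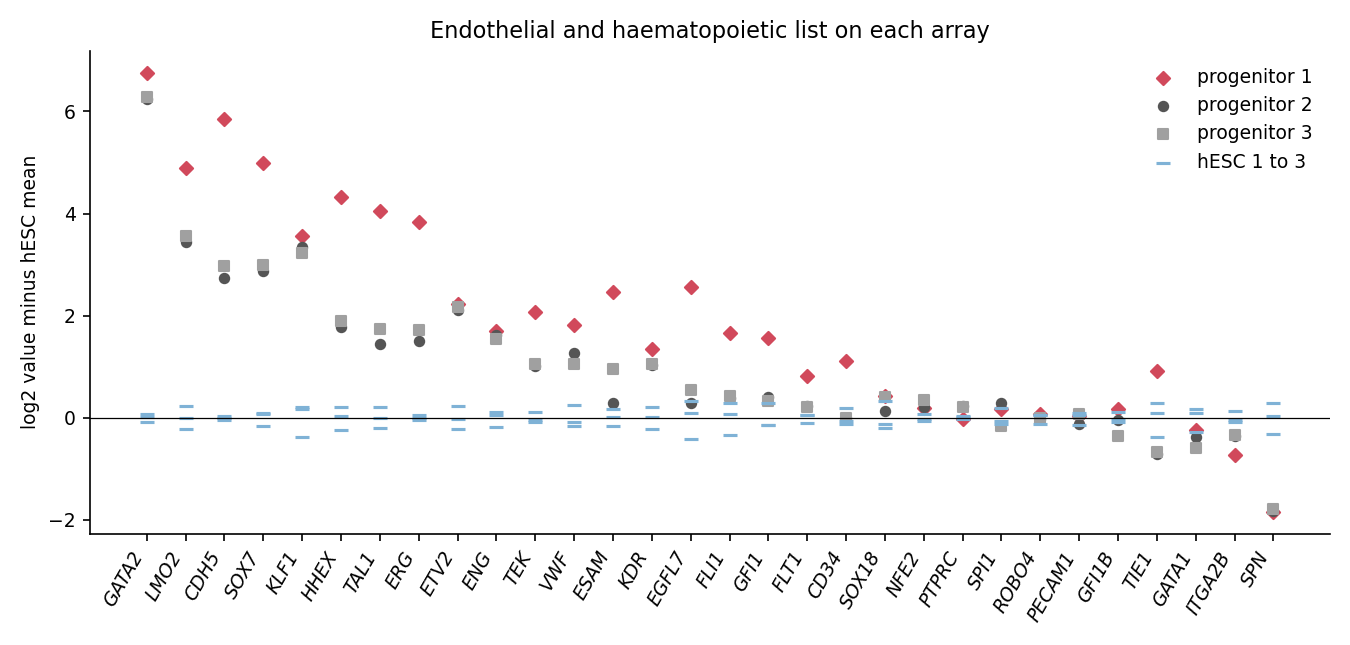
Log2 level of each of the 30 measured endothelial and haematopoietic genes minus its hESC mean, with a marker for each progenitor array and dashes for the 3 hESC arrays. Of the 30 genes, 26 were higher on progenitor array 1 than on the mean of the other progenitor arrays, as for CDH5 at 10.01 against 6.90 and 7.12.

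Endoderm and neuroectoderm genes, markers of other lineages that such a culture can hold, showed no common shift. Of 20 endoderm genes 7 rose, 4 fell and 9 did not pass, also adjusted over the list alone (median -0.02, mean 0.47 with the test pointing up, camera adjusted p = 0.642). SOX17, a factor of endoderm and haemogenic endothelium, rose by 2.36 (SE 0.14), PRDM1 by 2.79 and HHEX by 2.67, while the stem cell factor receptor KIT fell by 2.00, and so did AFP (-0.58), PDX1 (-0.56) and FOXA3 (-0.49), chosen after their values were seen. With scaling on hybridization controls AFP (-0.041) and PDX1 (-0.30) did not pass and FOXA3 turned, to 0.037, without passing, and PDX1 did not pass without hESC array 1 either (-0.51, adjusted p = 0.0519). HHEX was at 9.33 on progenitor array 1 and at 6.78 and 6.90 on the other progenitor arrays, and rose by 1.83 without array 1. The increase of SOX17 depended on the probe set, since without progenitor array 1, 2 or 3 another of its probe sets was the brightest and rose by 0.96, 0.95 or 0.91. Of 23 neuroectoderm genes 3 rose, 7 fell and 13 did not pass, with 2 higher and 5 lower adjusted over the list alone (median 0.01, mean -0.22 with the test pointing down, camera adjusted p = 0.381). SOX3 and POU3F1 fell, at -3.17 and -2.21, LHX2 rose by 1.67, as did NES (0.42) and SOX10 (0.36), chosen after their values were seen, and POU3F1 did not pass when probe sets that can match several transcripts were left out (-0.10). NES did not pass with median centring (0.19). SOX10 lost its call under most alternatives, among them no normalization (0.29), median centring (0.14) and leaving out progenitor array 1 (0.27), 2 (0.40) or 3 (0.40) or hESC array 1 (0.37) or 2 (0.26). PAX6, a neural and eye factor, differed by 0.27 (SE 0.26) without passing, and by -0.011 without progenitor array 1.

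Of 20 trophoblast and amnion genes 8 rose, 2 fell and 10 did not pass, also adjusted over the list alone (median 0.14, mean 1.28, camera adjusted p = 0.0358). This call was lost at an adjusted p = 0.145 with an estimated correlation, without progenitor array 1 (0.0523) and without hESC array 3 (0.0600). The members with the largest increases were GATA2, ISL1, GATA3 (5.11) and TFAP2A (4.19), transcription factors that also act elsewhere, GATA2 in blood, ISL1 in heart and TFAP2A in neural crest. Of the 8 members that rose, 7 rose at least 2-fold, and not all of these are named here. Among the members left without the dimmer 50% of genes the median was 5.11, without a call (camera adjusted p = 0.254). The placental genes ERVW-1 (syncytin) and CYP19A1 (aromatase) did not pass, at 0.04 and -0.01. PGF, a placental growth factor, fell by 1.31 on its brightest probe set and rose by 3.75 on another. The other member that fell was TFAP2C (-0.66), chosen after its value was seen, which did not pass with scaling on hybridization controls (-0.14).

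Of 28 HOX genes, which pattern the body axis, 14 rose, none fell and 14 did not pass, also adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 in limma. The median was 0.33 (camera adjusted p = 0.00175, and adjusted p = 0.375 with an estimated correlation). Among the measured genes the largest increases lay in the HOXB cluster, with HOXB2 at 6.77, HOXB6 at 5.74, HOXB9 at 5.22 and HOXB8 at 4.75. Most HOXA genes are not analysed here, so the HOXB cluster cannot be compared with the HOXA cluster. HOXC6 and HOXD10 did not pass, at -0.66 and -0.09, although other probe sets of HOXD10 rose by 0.67 and 1.78. With array weights both passed as lower, at -0.94 and -0.24. On the mean of its probe sets HOXD10 passed as higher, at 0.79. HOXB8 did not pass when probe sets that can match several transcripts were left out (0.10). The list was higher on progenitor array 1 than on the other progenitor arrays by a median of 0.23, with -0.15 on progenitor array 3, and among the hESC arrays it was higher on array 2 by 0.19 and lower on array 1, at -0.12.

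**Figure D4:**
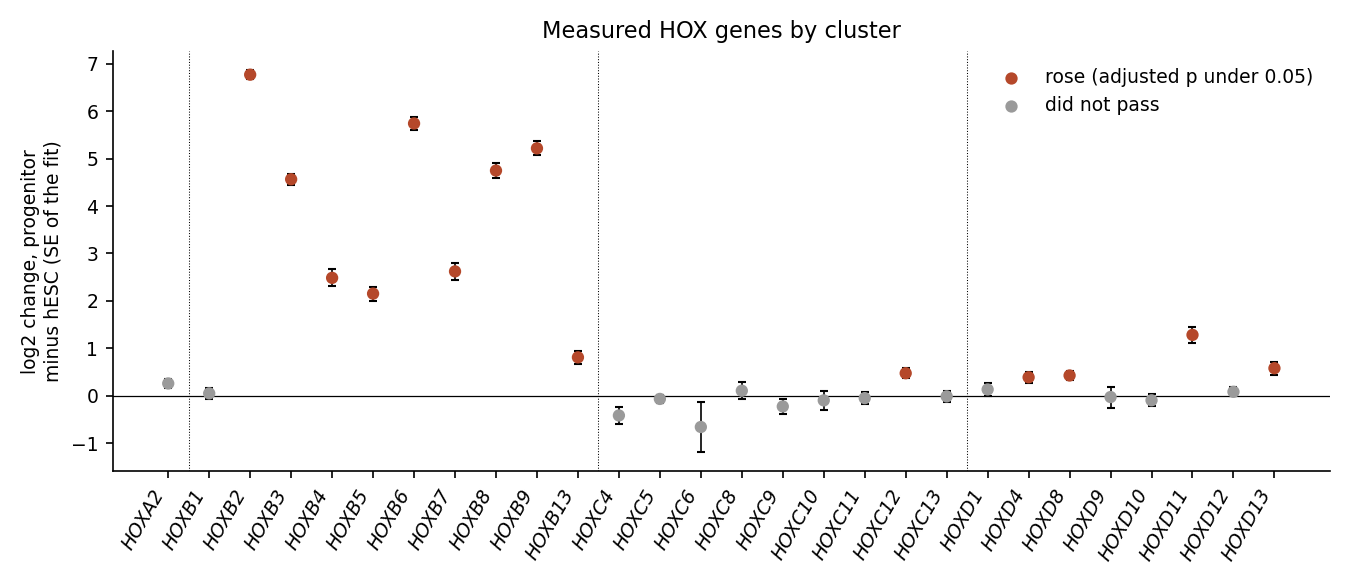
Log2 change of each measured HOX gene, progenitor minus hESC, by cluster, with bars for the standard error of the fit and colour for genes that rose. HOXB2, HOXB6, HOXB9 and HOXB8 rose by 6.77, 5.74, 5.22 and 4.75.

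Inhibitors of the cell cycle rose. Of 13 measured, 12 rose, none fell and 1 did not pass, also adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 in limma (median 1.04, camera adjusted p = 1.34e-05, and adjusted p = 0.0763 with an estimated correlation). The inhibitors of cyclin-dependent kinases CDKN1C and CDKN1A rose by 2.51 and 2.21, the growth arrest genes GADD45A and GADD45B by 2.47 and 2.24, and CDKN2A differed by 0.14 without passing. Of 30 cell cycle genes 10 rose, 13 fell and 7 did not pass, with 11 higher and 13 lower adjusted over the list alone, and no call (median -0.05, camera adjusted p = 0.366). These counts moved with the scaling, to 16 higher and 3 lower with scaling on hybridization controls and 6 higher and 14 lower with median centring. E2F1 and the replication genes MCM5 and CDC6 fell, at -1.34, -0.99 and -0.95, while the mitotic kinase CDK1 rose by 0.90. Relative to the other progenitor arrays, progenitor array 1 had a median of -0.11 for the cell cycle genes and of -0.18 for the inhibitors.

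Glycolysis genes showed no common shift on the quantile-normalized scale. Of 20 measured, 4 rose, 3 fell and 13 did not pass, also adjusted over the list alone (median 0.06, camera adjusted p = 0.870). PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 2.24, and the glucose transporter SLC2A1 and the enolase ENO2 fell, at -1.48 and -1.62. SLC2A1 did not pass when probe sets that can match several transcripts were left out (-0.30). PKM rose by 1.46, while another of its probe sets fell by 0.49. Chosen after their values were seen, PFKP (0.64) and PFKL (0.44) also rose, and HK2 (-0.75) fell, which did not pass on the mean of its probe sets (-0.27) or with scaling on hybridization controls (-0.30). None of 17 ribosomal protein genes passed the limma test, adjusted over all genes or over the list alone, and 0 had an unadjusted p under 0.05 (median 0.04, camera adjusted p = 0.958). RPS23 and RPS6 differed by 0.10 and 0.06, and passed, at 0.61 and 0.60, when arrays were scaled on hybridization controls. With that scaling all 17 ribosomal protein genes passed as higher (median 0.58). Of the glycolysis genes 16 were then higher and 2 lower (median 0.56). Neither list was called there (camera adjusted p = 0.0521 and 0.305).

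Genes of the dissociation and stress response rose. Of 21 measured, 13 rose, 1 fell and 7 did not pass, also adjusted over the list alone (median 0.81, camera adjusted p = 0.00102, and adjusted p = 0.0567 with an estimated correlation). The immediate-early genes FOS, EGR1 and JUNB rose by 2.93, 2.30 and 2.08 and KLF6 by 1.77, whereas KLF4, which also acts in pluripotency, fell by 1.13. A sort is named in the labels for the progenitors only. The biotin hybridization controls, 14 probe sets for transcripts added to the sample, were at 9.63 ± 0.11 (mean log2, SD, n = 3) in the progenitors and 10.15 ± 0.14 in hESC (exact permutation p = 0.1, the smallest possible). The cre controls, 4 further probe sets for an added transcript, were at 13.13 ± 0.09 in the progenitors and 13.26 ± 0.04 in hESC (difference -0.128, exact permutation p = 0.2). The 3' minus 5' difference of the actin control, a sign of RNA integrity and amplification, was 0.47 ± 0.05 in the progenitors and 0.76 ± 0.29 in hESC (exact permutation p = 0.1). For GAPDH the difference was -0.10 ± 0.09 and -0.17 ± 0.02 (exact permutation p = 0.3).

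Of the 22 lists, 13 were called with camera at the preset correlation, 11 higher and 2 lower in the progenitors. With an estimated correlation 6 of the 13 remained called, those of pluripotency, primitive streak, lateral plate and mesenchymal genes and of BMP and WNT targets. These 6 are not independent results, since members were also on other lists. This held for 14 of 26 listed streak genes, 10 of 26 lateral plate genes, 7 of 21 BMP targets and 5 of 20 WNT targets. It also held for 8 of 33 pluripotency and 5 of 25 mesenchymal genes. HAND1 and TBX3 were on both the lateral plate and BMP lists, and TBXT, SP5 and DKK1 on both the streak and WNT lists.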

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

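The tests of an array-wide difference and of a later stage for progenitor array 1, and those of the hybridization controls and of the stress genes, were chosen only after the result was seen. PLXND1, HEG1 and PECAM1, named below, were chosen after their values were seen.

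Signal also appeared outside the genes tested. Among 11721 probe sets not listed with a gene, 265 were higher at least 2-fold in the progenitors, and 1372 were lower, of 3388 that changed. Among 1801 probe sets annotated to several genes, 95 were higher at least 2-fold and 165 lower, of 703 that changed.

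With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 9463 changed genes, 5278 higher and 4185 lower, with 1857 and 1427 at least 2-fold, and for each of these counts 1 of the 10 splits, the real one, gave as many. The highest of the other 9 splits gave 0 genes with limma, with 134 to 389 genes at an unadjusted p under 0.05, against 10582 in the real split. For the gene lists, 2 of the 10 splits called as many as the real one, 13 lists, and the highest other split, which set progenitor arrays 1 and 3 with hESC array 2 against the rest, also called 13. Each of the other 9 splits had arrays of both groups on both sides, so the difference between the groups became spread within the sides. Gene counts near 0 were thus set in advance. These splits also keep a part of the group difference, so neither their gene counts nor their list counts measure chance.

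The endothelial and haematopoietic genes were higher on progenitor array 1 than on the other progenitor arrays, by a median of 0.54. A separate list of endothelial genes, written down before its values on single arrays were looked at, was higher there as well (median 0.40, 19 of 23 higher). It lay at percentile 100 of 10000 random lists matched on mean expression, so it stood apart from random genes of like level. The percentile cannot decide on an array-wide difference of scale or background, since quantile normalization had already taken such a difference out of the matched lists. Random lists also do not hold genes that vary together. Other lists differed too, with cell cycle genes (median -0.11, 5 of 30 higher, percentile 0.1) and cell cycle inhibitors (-0.18, percentile 0.95) lower on that array and pluripotency genes (0.14, percentile 99.99), HOX genes (0.23, percentile 99.99), activin and nodal targets (0.20, percentile 99.87) and matrix genes (0.067, percentile 99.46) higher, and percentiles as far out occurred on other arrays, as for matrix genes on hESC array 2 (0.15, percentile 100). The second list is consistent with more cells with an endothelial transcript programme in the sample, with PLXND1 at 10.46 against 9.87 and 9.88, while HEG1, at 9.95, lay between the other arrays and PECAM1, abundant in endothelium, was at 6.08 against 5.93 and 6.13, but the gate would have removed endothelial cells without CD56 or with CD326, a higher level per cell would look alike, and 3 of the 30 genes belong to other lists too. Open too is a culture that had moved further from the streak stage, since the streak list lay at percentile 9.9 on that array, and the design names no difference between the progenitor samples. On progenitor arrays 2 and 3 the streak list lay at percentiles 99.91 and 98.12, each against a mean that includes array 1.

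The biotin hybridization controls were lower on the progenitor arrays by a mean log2 difference of -0.528, on all 14 probe sets without overlap, while the 4 cre controls differed by -0.128, on 2 probe sets without overlap. One possible explanation is a different scale of these arrays that a scaling by the authors took out of the genes, and another is a different ratio of added control to sample RNA. They cannot be told apart here, because the deposited values do not show the level of the genes before such a scaling, and while a common factor would have moved the cre controls alike, these lay near the highest intensities of the arrays (11417 to 12340), where saturation would hide a difference. When arrays were scaled on these controls instead, 9102 genes were higher and 2002 lower, so the share of genes called in each direction depends on that choice.

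The dissociation and stress genes were higher in the progenitors, with a median of 0.81. Handling during dissociation and sorting may have raised them, and so may a response to the growth factors, since EGR1 and IER3 also belong to the FGF and ERK list. They cannot be told apart, because sorting and group are the same split of the samples. The list lost its call at an adjusted p = 0.0567 with an estimated correlation, the highest over its alternatives, which began at 8.36e-05.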

How the results depend on the processing

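The average of progenitor arrays 2 and 3 and the scaling on hybridization controls were chosen only after the result was seen. Of 3674 values of 198 named genes under other settings, 145 of them named by the rule, 3534 kept their side of the threshold and, where called, their direction, 43 lost the call, 88 gained one and 9 turned, among genes called with or without the alternative. In place of 9463 changed genes there were 6858 to 12561 under the other settings of the gene test (8095 with progenitor arrays 2 and 3 as 1), and 7891 to 9348 when an array was left out. Testing probe sets singly gave 17836 changed, 9935 higher and 7901 lower, since more features were tested. Scaling on hybridization controls gave 9102 genes higher and 2002 lower, with 3473 and 815 at least 2-fold, and centring on the median gave 6447 lower, since both shift all genes. Leaving out the dimmer 50% of genes left 1202 genes higher at least 2-fold, since fewer genes were tested. With an estimated correlation the lists that lost their call had adjusted p-values of 0.465 (endothelial), 0.0841 (epithelial), 0.375 (matrix and HOX), 0.145 (trophoblast and amnion), 0.0763 (cell cycle inhibitors) and 0.0567 (stress). These were the highest values of the lists over all alternatives, except for trophoblast and amnion (range 0.00366 to 0.254), and the lowest were 0.000981 (endothelial), 1.39e-11 (epithelial), 0.000161 (matrix), 0.000423 (HOX), 6.83e-07 (inhibitors) and 8.36e-05 (stress). The endothelial list also lost it without the dimmer 50% (0.0825). The trophoblast and amnion list lost it there (0.254), with array weights (0.0774), with scaling on hybridization controls (0.110) and with ranks (0.103), and leaving out an array gave adjusted p-values of 0.0132 to 0.0600. The FGF and ERK list gained a call without normalization (0.0477) and with median centring (0.00807), within a range up to 0.209. Of the genes so called, those that turned were TBX5 without probe sets that can match several transcripts (0.053), PGF (1.22) and HOXD10 (0.79) on the mean of their probe sets, and CALD1 (0.37), ZNRF3 (0.011), LDHB (0.52), GAPDH (0.46), TPM1 (0.16) and FOXA3 (0.037) with scaling on hybridization controls. CALD1, a member of the mesenchymal list that was not called in the main setting, passed as lower on the mean of its probe sets (-0.99). For all of these lists and genes the cause was not tested. The deviations of arrays with the same replicate number correlated at -0.02, 0.03 and -0.04. They gave no sign that the numbers pair the samples, but cannot exclude a shared culture or day. The replicate number as a block gave 8880 changed genes and changed no list call. Levels near the floor of the deposited values limit what can be said of dim genes.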

Other observations

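The test of the HOX clusters was chosen only after the result was seen, as were all gene families and the genes named for them.

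Several gene families held members that moved in opposite directions. The family members named here, other than GATA1, TET1 and TET3, kept their call and direction when arrays were not normalized. They also kept both when arrays were centred on the median of their gene values or were scaled on hybridization controls. Among 25 integrin subunits 7 rose and 6 fell, with ITGA8 (4.18), ITGA5 (3.22) and ITGA9 (3.10) higher and the laminin receptors ITGA7 (-3.62) and ITGA6 (-2.51) lower. The hyaluronan synthase HAS2 rose by 5.88 and HAS3 fell by 4.05, and the link protein HAPLN1 rose by 7.12 while HAPLN3 fell by 1.74. Of 9 Frizzled receptors 5 rose and 3 fell, with FZD1 (3.98) and FZD4 (1.97) among the higher and FZD5 (-3.03) and FZD3 (-1.22) among the lower. Of 17 WNT ligands 4 rose, WNT5A (4.99), WNT5B (3.66), WNT4 (3.32) and WNT11 (2.29), and WNT9A fell by 1.25. Among the Eph receptors EPHB3 rose by 3.65 and EPHA1 fell by 3.56. The counts moved with the scaling, from 5 to 9 integrins higher and 3 to 9 lower, 4 or 5 Frizzled receptors higher and 2 to 4 lower, and 4 to 7 WNT ligands higher and 1 to 4 lower.

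The GATA and KLF factors moved mostly one way. Of 6 GATA factors 5 rose, all at least 2-fold, and GATA1, not called (-0.40, adjusted p = 0.0575), was lower under 5 alternatives, those without normalization (-0.50), with median centring (-0.65), with array weights (-0.62), without the dimmer 30% of genes (-0.40) and without hESC array 2 (-0.54). Of 17 KLF factors 11 rose and 1, KLF4, fell, with 3 lower under median centring, and KLF1 (3.38), KLF5 (3.22) and KLF8 (2.38) had the largest increases. Forkhead factors and enzymes of DNA methylation moved both ways. Of 39 forkhead factors 10 rose and 8 fell, with 9 and 9 without normalization, 8 and 13 with median centring and 16 and 3 with scaling on hybridization controls, and FOXF1, a marker of splanchnic mesoderm, rose by 6.04. Of 7 enzymes of DNA methylation, the methyltransferases DNMT3B and DNMT3A fell by 1.93 and 0.98, while TET2, which oxidises methylated cytosine, rose by 1.06. Of its relatives, TET3 rose by 0.36, but did not pass with median centring (0.23), nor without progenitor array 2 (0.34) or 3 (0.36) or hESC array 1 (0.36) or 3 (0.27), among other settings, and TET1 fell by 0.79, but did not pass with scaling on hybridization controls (-0.33).

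Of 10 measured HOXB genes 8 rose at least 2-fold, against 1 of 17 measured HOXC and HOXD genes, HOXD11. A two-sided Fisher's exact test of these counts gave p = 0.000165, but the clusters were compared because of the values of the same genes, and genes of a cluster are not independent, so the test adds nothing to the counts. Under no normalization, median centring and scaling on hybridization controls 9 HOXB genes rose in each case, and 4, 1 and 5 HOXC and HOXD genes rose, with 1 lower under median centring. Most HOXA genes are not analysed here.

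On progenitor array 1, 148 genes were more than 2-fold above the mean of the other progenitor arrays, against 2 genes for array 2 and 1 for array 3. Those with the largest deviations included ECSCR, at 9.55 against 6.27 and 6.71, ICAM2, at 9.10 against 6.08 and 6.27, and CDH5. ECSCR and ICAM2 were chosen after their values were seen. The difference of ECSCR between the groups did not pass the test (0.82, adjusted p = 0.479), and its levels in hESC were 7.06, 5.70 and 7.31. Without progenitor array 1 it turned to -0.20, again without passing (adjusted p = 0.776).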
